A study of Mus musculus with 7 samples.

How the data were processed

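Total RNA of 3 wild-type neocortex and 4 astrocytoma samples was isolated with a miRNA isolation kit and measured with the NanoString nCounter mouse miRNA assay, version 1.3 of the panel, per the labels and design text. The deposited values are log2 values, 1 column per sample, with 2 decimals. The normalization, background correction and software behind them are not given in the sources used here. The values themselves show more. In each sample the deposited log2 values at the low end, taken back to the linear scale, were whole multiples of 1 number. Of the 151 to 264 values checked per sample, up to 60 counts, 100% were whole within a tolerance of 0.02 counts plus the rounding of the deposited decimals. A single count was worth 1.79, 2.94 and 4.64 linear units in neocortex 1, 2 and 3, and 0.961, 0.728, 0.859 and 0.530 in tumor 1 to 4. The linear mean of the 100 brightest miRNA probes was 990 to 1012 in all samples, so the scaling equalized the bright miRNAs.

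Every probe under a cutoff of its sample was listed at 0. The cutoff lay at 14, 10 and 8 counts in neocortex 1, 2 and 3 and at 13, 13, 16 and 16 counts in tumor 1 to 4. The larger factors of the neocortex samples put it at 4.65, 4.88 and 5.21 on the log2 scale there, against 3.64, 3.24, 3.78 and 3.09 in the tumors. The highest positive-control probe had 10273 to 14878 counts in neocortex and 13105 to 16902 in tumor. On the normalized scale the mean of the 5 highest positive-control probes differed by -1.71, tumor minus neocortex (2-sided exact permutation p = 0.0286, 35 splits of the 7 samples). The recovered counts give each sample's total and the precision of low probes. Because the deposited values are on a log scale, no count model was run.

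The groups and replicate numbers were taken from the sample labels. The comparison of tumor with neocortex was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided) on the log2 values as deposited, with no covariate and no pseudocount. Benjamini-Hochberg adjustment ran over the miRNAs tested. Control, mRNA and viral probes were left out. A miRNA was tested where its mean over the 7 samples was at least the median of that mean over all 566 miRNA probes, 2.80, which left 283. Probes that name several miRNAs, 9 in number, were kept as 1 feature each. As a value of 0 stands for a level anywhere under the cutoff, no fold is given against a group at 0 in every sample; the tumor mean is set against the mean neocortex cutoff instead, as a lower bound. The limma and camera tests, the lists, the naming rule and most alternatives were fixed before the data were examined. Alternatives added afterwards were raising all values to the highest cutoff, keeping only miRNAs above the cutoff in all 7 samples, subtracting the negative-control probe NEG_D and then applying the highest cutoff, and leaving out neocortex 3 or tumor 1 with the shared cutoff. The tests of background counts were chosen after the data were examined but before their own results were seen. Chosen after their results were seen were the interval required of the background slope, the tests of miRNAs at 0 in all neocortex samples, and those of the oligodendrocyte-enriched list against neuron-enriched miRNAs and against the median of all miRNAs.

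The 15 miRNA lists were written from general knowledge. They are neuron-enriched, oligodendrocyte-enriched, astrocyte-enriched, microglia and white blood cell, red blood cell, endothelial and mural, fibroblast and mesenchymal, epithelial and choroid plexus, other tissue, miR-17-92 and paralogs, let-7, raised in gliomas, lowered in gliomas, Dlk1-Dio3 and Sfmbt2. Some miRNAs stand on more than 1 list. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 15 lists, and again with an estimated correlation and with fry.

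Named miRNAs follow a fixed rule. In each direction it takes the 10 miRNAs with the largest change among those past an adjusted p of 0.05 whose groups do not overlap. It adds the 2 most abundant tested members of each list, a fixed set (miR-21, miR-124, miR-128, miR-9, miR-10b, miR-7a, miR-34a, miR-137, miR-219, miR-338-3p, miR-142-3p, miR-126-3p, miR-146a, miR-155 and miR-451) and the 3 most abundant miRNAs of each group. List members outside the rule are named where they complete a count and were then chosen after their values were seen. Of the 566 probes, 532 matched a miRNA gene of that name in the GRCm38.p6 gene table, which was used for names only.

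The alternatives comprised scaling on the median, on the 100 brightest miRNAs, by quantiles, on positive-control probes and on housekeeping mRNA probes. B2m had a value of 0 in neocortex 3, so the housekeeping factor used Actb, Gapdh and Rpl19. They also comprised filters, background subtraction, pseudocounts, a trend and robust fit, sex, male samples only, a replicate block, a minimum log2 change of 1, and each sample left out in turn.

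The fit was tested on simulated data for this comparison, with 20 runs, each with 80 changed miRNAs or none. With the values as listed it recovered 67.4% of log2 changes of 1 and 94.5% of log2 changes of 2, with means of 283 miRNAs tested. With no miRNA changed it still made a mean of 10.8 higher calls per run, as the cutoffs differ between the groups. With the shared cutoff it recovered 79.0% and 97.8%, and made a mean of 0.05 higher calls with no change, over a mean of 215 miRNAs tested. The changed miRNAs were drawn only from those whose mean listed level lay above every cutoff. The recovery rates therefore do not cover miRNAs near or under a cutoff. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.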

Results

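MicroRNA levels were compared between normal mouse neocortex and astrocytoma. The 3 normal samples were upper cortical layers (II to IV) of wild-type CD1 mice at postnatal day 60. The 4 tumor samples came from CD1 mice carrying a transgene that places an activated Ras oncogene under the human promoter of GFAP, an astrocyte filament gene, and were taken at postnatal days 65, 104, 125 and 134. Neocortex sample 2 and tumor 2 were female and the other 5 samples male. Total RNA was measured with the NanoString nCounter mouse miRNA assay, which counts color-coded probes without amplification. Of the 566 mouse miRNA probes on the panel, 283 had a mean level high enough to be tested.

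The tumor samples gave more miRNA counts. Total recovered miRNA counts were 60792, 37000 and 23556 in the neocortex samples, and 117609, 152589, 128499 and 208126 in the tumors (2-sided exact permutation p = 0.0286, the smallest that 3 against 4 samples allow). The highest positive-control probe averaged 12827 counts in neocortex and 14884 in tumor (2-sided exact permutation p = 0.229). The 1.16-fold difference of that probe, against 3.75-fold for the miRNA totals, argues against counting depth alone as the source of the higher totals. RNA input and miRNA content were not separated as sources. Between 248 and 252 miRNA probes lay above the cutoff of each neocortex sample, against 353 to 424 in each tumor. On the deposited scale that cutoff averaged 4.91 ± 0.28 in neocortex (SD, n = 3) and 3.44 ± 0.33 in tumor (SD, n = 4), and every probe under it was listed at 0. A miRNA at the same normalized level could therefore be listed in a tumor and be at 0 in neocortex. Over probes above the cutoff in both samples of a pair, Pearson's r across miRNAs was 0.929 to 0.966 within neocortex, 0.946 to 0.979 within tumor and 0.887 to 0.938 between them; miRNAs are not independent replicates.

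**Figure D1:**
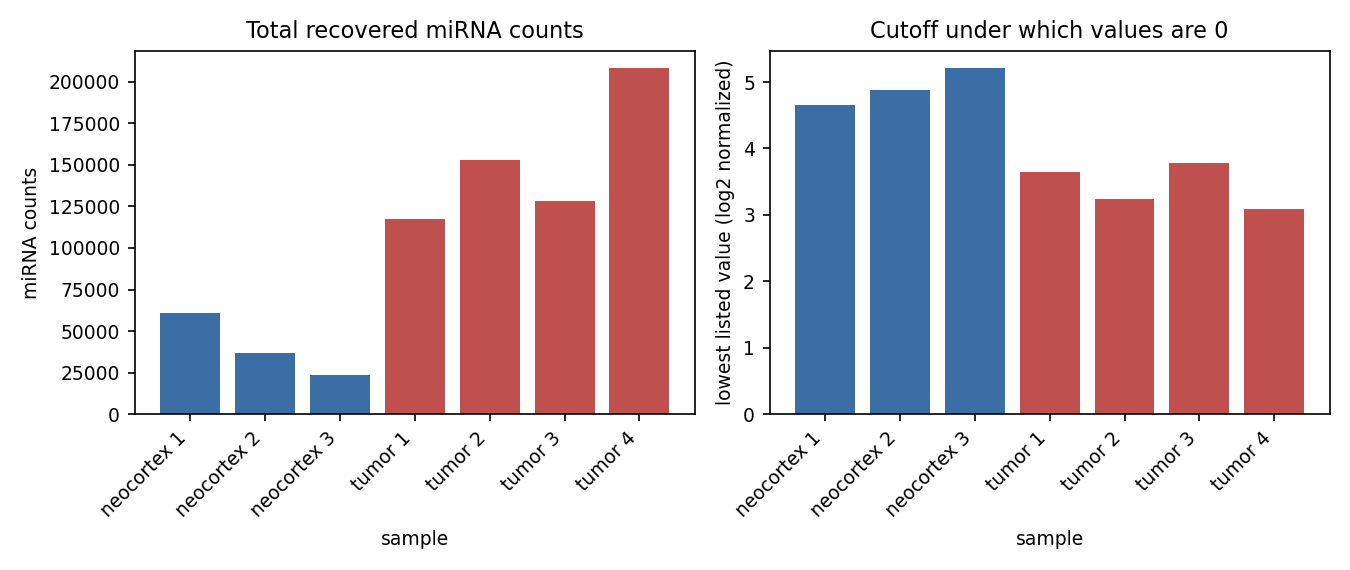
Total recovered miRNA counts (left) and the lowest listed value on the log2 normalized scale (right), 1 bar per sample, neocortex in blue and tumor in red. All 4 tumors lie above all 3 neocortex samples in counts, 117609 to 208126 against 23556 to 60792, and below them in cutoff, 3.09 to 3.78 against 4.65 to 5.21.

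The comparison of astrocytoma with adult neocortex asks which miRNAs differ between the tumor and the gray matter. The clearest differences were a higher level of miR-21, a miRNA often raised in cancers and in reactive glia, and lower levels of miR-219 and miR-338-3p, which promote oligodendrocyte maturation. miR-21 was 6.79-fold higher in tumor, with log2 means of 9.22 ± 0.32 in neocortex (SD, n = 3) and 11.99 ± 0.39 in tumor (SD, n = 4). miR-219 and miR-338-3p fell by 2.19 and 2.08 on the log2 scale. miR-9, abundant in neural progenitors and in mature brain, rose 2.33-fold, and the shared probe of miR-106a and miR-17, members of growth-promoting clusters, rose 2.61-fold. In all, 23 miRNAs were higher and 27 lower in tumor at a Benjamini-Hochberg adjusted p under 0.05 in limma. All 50 had every tumor value on one side of every neocortex value, as did 93 of the 283 tested miRNAs, where chance gives 5.71%. For 8 of the 23 higher ones this follows from being listed at 0 in all neocortex samples. Calls chosen on the same values tend to be separated, so the separation adds no support to them.

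The number of calls depended on how 0 values and scaling were handled. With every value under the highest cutoff of the 7 samples, 5.21, raised to it (called the shared cutoff here), 23 miRNAs were higher and 33 lower of 204 tested, and 15 of the higher and 20 of the lower calls were shared with the values as listed. Directions are relative to the authors' scaling: on the positive-control probes 228 miRNAs were higher and 0 lower in limma (231 and 0 at an unadjusted p under 0.05; median of all tested miRNAs 1.74 against 0.03), and on the housekeeping mRNA probes 10 were higher and 135 lower (median -0.93). Without neocortex 1 there were 32 higher and 41 lower calls, without neocortex 3 there were 23 and 14, and without tumor 2, 3 or 4 there were 13 and 10, 13 and 16, or 15 and 22.

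**Figure D2:**
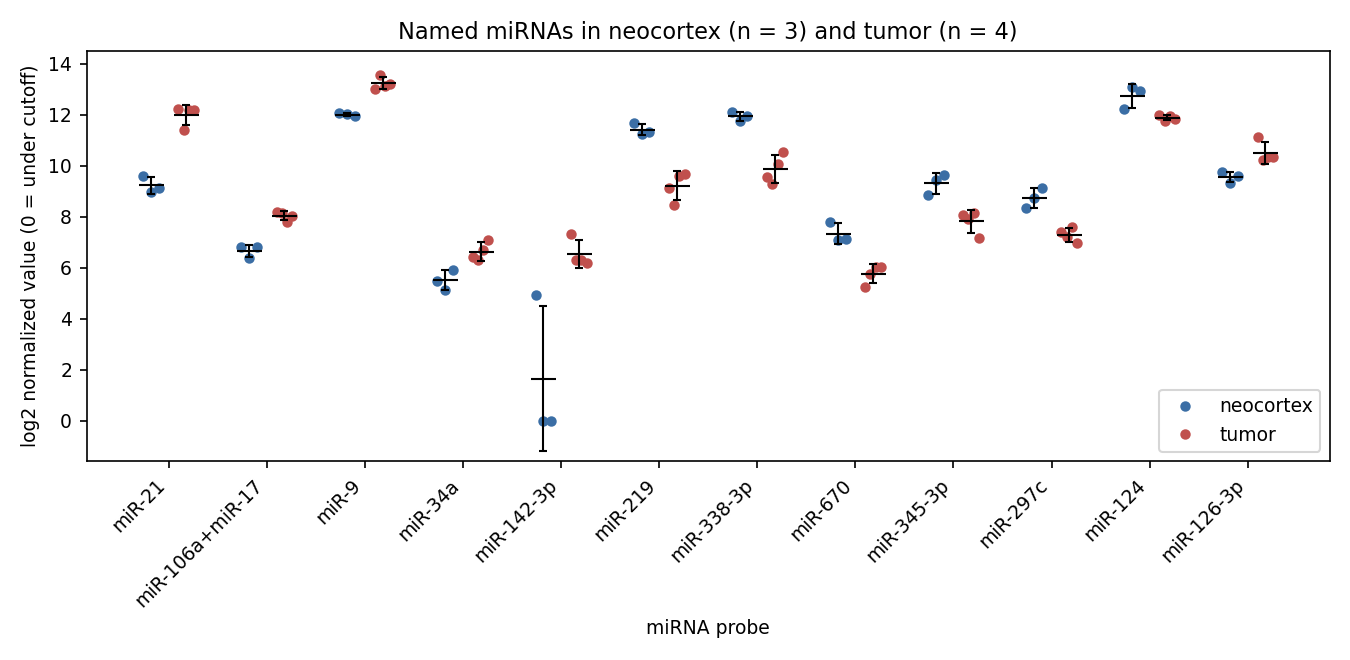
Log2 normalized values of 12 miRNA probes in each neocortex (blue, n = 3) and tumor sample (red, n = 4); black bars show the mean ± SD, and 0 means under the cutoff. The tumor values of miR-21, 11.40 to 12.20, lie above the neocortex values, 8.98 to 9.59, and those of miR-219, 8.47 to 9.68, below 11.23 to 11.65. Scaled on the positive-control probes, miR-670, miR-345-3p, miR-297c and miR-124 lie above 0 in tumor over neocortex.

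All 3 oligodendrocyte-enriched miRNAs on the panel fell in tumor on the authors' scaling. miR-219 had a log2 mean of 11.40 ± 0.22 in neocortex (SD, n = 3) and 9.21 ± 0.56 in tumor (SD, n = 4), with a log2 change of -2.19 (SE 0.34, adjusted p = 0.0091 in limma, Benjamini-Hochberg). miR-338-3p changed by -2.08 (SE 0.33, adjusted p = 0.0098 in limma, Benjamini-Hochberg) and miR-338-5p, the other strand of the same precursor, by -1.39 (SE 0.30, adjusted p = 0.028 by the same test). miR-338-5p had a mean of 31.7 counts in neocortex and was too low to test with the negative-control probe NEG_D subtracted and the shared cutoff applied together, though it passed with the shared cutoff alone. Its adjusted p was 0.059, 0.062, 0.077 or 0.060 without neocortex 2, neocortex 3, tumor 2 or tumor 4 (limma, Benjamini-Hochberg). The list was lower than the other tested miRNAs in limma's camera (median -2.08, Benjamini-Hochberg adjusted p = 0.024), with adjusted p = 0.47 with an estimated correlation. All 3 calls also held adjusted over the list alone. Without neocortex 1, neocortex 2 or tumor 1 the adjusted p of the list in camera was 0.13, 0.067 or 0.0504 (Benjamini-Hochberg). Scaled on the positive-control probes, miR-219 and miR-338-3p lay at -0.48 and -0.37 and miR-338-5p above 0, at 0.32, and none of them passed the test.

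Neuron-enriched miRNAs were not called as a group in camera. Of 20 tested members 1 was higher, 0 were lower and 19 did not pass the test in limma, with 1 higher and 0 lower adjusted over the list alone and 1 higher and 3 lower at an unadjusted p under 0.05. The list's median was -0.27 and its mean 0.00, with 14 members below 0 and 6 above, and camera gave the direction down (Benjamini-Hochberg adjusted p = 0.41). That mean includes members at 0 in some neocortex samples, with changes of up to 2.21. Over the 17 members above the cutoff in all 7 samples the mean differed by -0.27 (SE 0.24). The member called higher was miR-9, with a log2 change of 1.22 (SE 0.19, adjusted p = 0.0091 in limma, Benjamini-Hochberg). miR-124, a neuron-specific miRNA, had log2 means of 12.73 ± 0.46 in neocortex (SD, n = 3) and 11.88 ± 0.11 in tumor (SD, n = 4); its change of -0.85 had a limma Benjamini-Hochberg adjusted p = 0.060, and 0.024 with the shared cutoff. miR-128 and miR-137 differed by -0.75 and -0.28 and did not pass the test. Leaving out neocortex 1 put miR-124 at -1.12 (adjusted p = 0.0068), and leaving out tumor 1 put miR-128 at -0.997 (adjusted p = 0.034; both limma, Benjamini-Hochberg). Scaled on the housekeeping probes, miR-9 was still higher, by 0.26, without passing the test, and on the positive-control probes miR-124, miR-128 and miR-137 lay above 0.

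The miR-17-92 cluster and its paralogs, which drive proliferation in many tumors, were higher in tumor as a group. All 7 tested members had values above 0 for tumor over neocortex, 4 of them rose over all miRNAs tested and 7 adjusted over the list alone. The miR-106a and miR-17 probe changed by 1.38 (SE 0.20, adjusted p = 0.0079 in limma, Benjamini-Hochberg). The other 3, miR-19b at 1.11, the miR-20a and miR-20b probe at 1.14 and miR-93 at 0.87, are named because they completed the count and were chosen after their values were seen. Each of these 3 lost its call in most fits that left out 1 sample (limma, Benjamini-Hochberg): miR-19b and miR-93 without any sample but tumor 1, with adjusted p of up to 0.10 and 0.12 (miR-93 also 0.053 with median scaling and 0.054 with no filter), and the miR-20a and miR-20b probe without any but neocortex 3 or tumor 4, up to 0.11. With sex as a covariate miR-19b, the miR-20a and miR-20b probe and miR-93 had adjusted p of 0.051, 0.069 and 0.069 (limma, Benjamini-Hochberg). On the housekeeping probes they lay at 0.15, 0.18 and -0.09 and did not pass the test. miR-25 differed by 0.53 and did not pass over all miRNAs, and with NEG_D subtracted and the shared cutoff applied it rose by 1.10. The median was 0.97 and camera gave a Benjamini-Hochberg adjusted p of 0.0043, with adjusted p = 0.47 with an estimated correlation. Without neocortex 2 the list's camera adjusted p was 0.053 (Benjamini-Hochberg), and scaled on the housekeeping probes its median was 0.012, with 4 members above 0 and 3 below.

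miRNAs reported as raised or lowered in gliomas matched their list's name only in part. In the raised list 3 of 12 tested members were higher and 0 lower (3 and 1 adjusted over the list alone; 3 and 1 at an unadjusted p under 0.05 in limma), with a median of 0.23 and a camera adjusted p of 0.24 (Benjamini-Hochberg). They were miR-21, with a log2 change of 2.76 (SE 0.28, adjusted p = 0.0018 in limma, Benjamini-Hochberg), miR-93, whose adjusted p reached 0.12 when any sample but tumor 1 was left out, and miR-196a, which was at 0 in all neocortex samples. miR-26a differed by 0.01, and miR-155 had log2 means of 6.96 ± 0.42 in neocortex (SD, n = 3) and 7.12 ± 0.70 in tumor (SD, n = 4). miR-10b, high in human gliomas, was at 0 in all neocortex samples and in tumor 3, lay between 3.48 and 3.85 in the other tumors, and was too low to test. In the lowered list 3 of 16 tested members were lower and 1 higher (4 and 1 adjusted over the list alone), with a median of -0.35 and a camera adjusted p of 0.24 (Benjamini-Hochberg). The 3 lower were miR-181a at -0.99, miR-181c at -0.93 and the probe of miR-181b and miR-181d at -1.27, which were chosen after their values were seen. The latter 2 had means of 27.32 and 19.99 counts in neocortex and were too low to test with NEG_D subtracted and the shared cutoff applied, the last of them with the shared cutoff alone as well. Scaled on the positive-control probes all 3 lay above 0, at 0.72, 0.79 and 0.44, and miR-181c was called higher there (adjusted p = 0.027 in limma, Benjamini-Hochberg). Scaled on the median, miR-181a and the probe of miR-181b and miR-181d had adjusted p of 0.14 and 0.090, by quantiles 0.054 and 0.10, and the probe 0.087 in the trend and robust fit and 0.065 with the negative-control mean subtracted (all limma, Benjamini-Hochberg). Their limma Benjamini-Hochberg adjusted p lay above 0.05 without any single sample but tumor 4 for miR-181a and for the probe of miR-181b and miR-181d, up to 0.11 for each, and without neocortex 3, tumor 2 or tumor 3 for miR-181c, up to 0.066. The higher one was miR-34a, a p53 target, at 1.12 (SE 0.29, adjusted p = 0.044 in limma, Benjamini-Hochberg). Its adjusted p lay above 0.05 without any single sample other than neocortex 3, reaching 0.12 without tumor 3 (limma, Benjamini-Hochberg). miR-7a differed by 0.06.

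Markers of immune cells gave 2 calls and markers of vessel cells none in limma with the values as listed, and camera called neither list. miR-142-3p, specific to blood-derived cells and microglia, was at 0 in neocortex 2 and 3, at 4.93 in neocortex 1 and at 6.18 to 7.33 in the tumors. It was called with the values as listed (adjusted p = 0.044 in limma, Benjamini-Hochberg; up to 0.11 when any sample but neocortex 1 was left out; 0.055 with a pseudocount of 0.5), and with the shared cutoff it rose by 1.31 (SE 0.28, adjusted p = 0.011 by the same test). miR-146a, induced by inflammatory signals, was at 0 in all neocortex samples and at 5.72 ± 0.31 in tumor (SD, n = 4); with the shared cutoff it differed by 0.51 (SE 0.19, adjusted p = 0.086 in limma, Benjamini-Hochberg) and lost its call. Of 7 tested microglial and white blood cell miRNAs these 2 were higher and 0 lower (2 and 0 adjusted over the list alone; 2 and 0 at an unadjusted p under 0.05), or 1 and 0 with the shared cutoff, with a median of 0.32 and a camera adjusted p of 0.28 (Benjamini-Hochberg); miR-342-3p and miR-150 differed by -0.54 and -0.49, and without neocortex 1 miR-342-3p by -0.82 (adjusted p = 0.023 in limma, Benjamini-Hochberg). miR-126-3p, the main endothelial miRNA, had log2 means of 9.55 ± 0.20 in neocortex (SD, n = 3) and 10.49 ± 0.42 in tumor (SD, n = 4), with limma Benjamini-Hochberg adjusted p = 0.060 as listed and 0.023 with the shared cutoff. The 4 vessel miRNAs had a median of 0.45 with none past the test (1 adjusted over the list alone, 1 at an unadjusted p under 0.05), and camera gave an adjusted p of 0.41 (Benjamini-Hochberg). The 3 red blood cell miRNAs had a median of 0.71 with 0 calls in limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, and camera gave an adjusted p of 0.32 (Benjamini-Hochberg); miR-451 and miR-144 differed by 0.71 and 0.70, and with NEG_D subtracted and the shared cutoff applied by 1.06 and 1.63, which passed the test.

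Astrocyte-enriched miRNAs had values above 0 in 5 of 7 tested members, with 0 called in limma (0 adjusted over the list alone and 2 at an unadjusted p under 0.05). Their median was 0.66, or 0.40 over the 5 tested with the shared cutoff, and camera gave an adjusted p of 0.32 (Benjamini-Hochberg). miR-29b and miR-29a, abundant in mature astrocytes, differed by 0.70 and 0.66, with limma Benjamini-Hochberg adjusted p = 0.060 and 0.10 as listed and 0.024 and 0.046 with the shared cutoff. The 3 fibroblast and mesenchymal miRNAs had 0 calls in limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, with a median of -0.22 and a camera adjusted p of 0.85 (Benjamini-Hochberg); miR-145 and miR-143, both also on the vessel list, differed by -0.22 and 0.40. The 6 epithelial and choroid plexus miRNAs had 0 calls by each of these counts, a median of 0.39, or -0.60 over the 4 tested with the shared cutoff, and a camera adjusted p of 0.85 (Benjamini-Hochberg); miR-204 and miR-34c differed by -0.09 and -0.47, and without neocortex 2 miR-34c by -1.85 (adjusted p = 0.024 in limma, Benjamini-Hochberg). Of 6 tested muscle, liver and embryonic stem cell miRNAs 1 was lower and 0 higher (1 and 0 adjusted over the list alone; 1 and 1 at an unadjusted p under 0.05), with a median of 0.67, or -0.84 over the 2 tested with the shared cutoff, a mean of 0.40, a camera direction of down and an adjusted p of 0.85 (Benjamini-Hochberg). The lower one, the embryonic stem cell miRNA miR-291b-3p, was counted at a mean of 38.4 counts in neocortex; its change of -1.56 became -0.63 (SE 0.19) with NEG_D subtracted and the shared cutoff applied. miR-302d, also from stem cells, had values of 5.36 to 5.53 in neocortex, was at 0 in tumor 1 and did not pass the test, except on the housekeeping probes (-3.29) and with a pseudocount of 10 or 30 (-1.41 and -0.83).

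**Figure D3:**
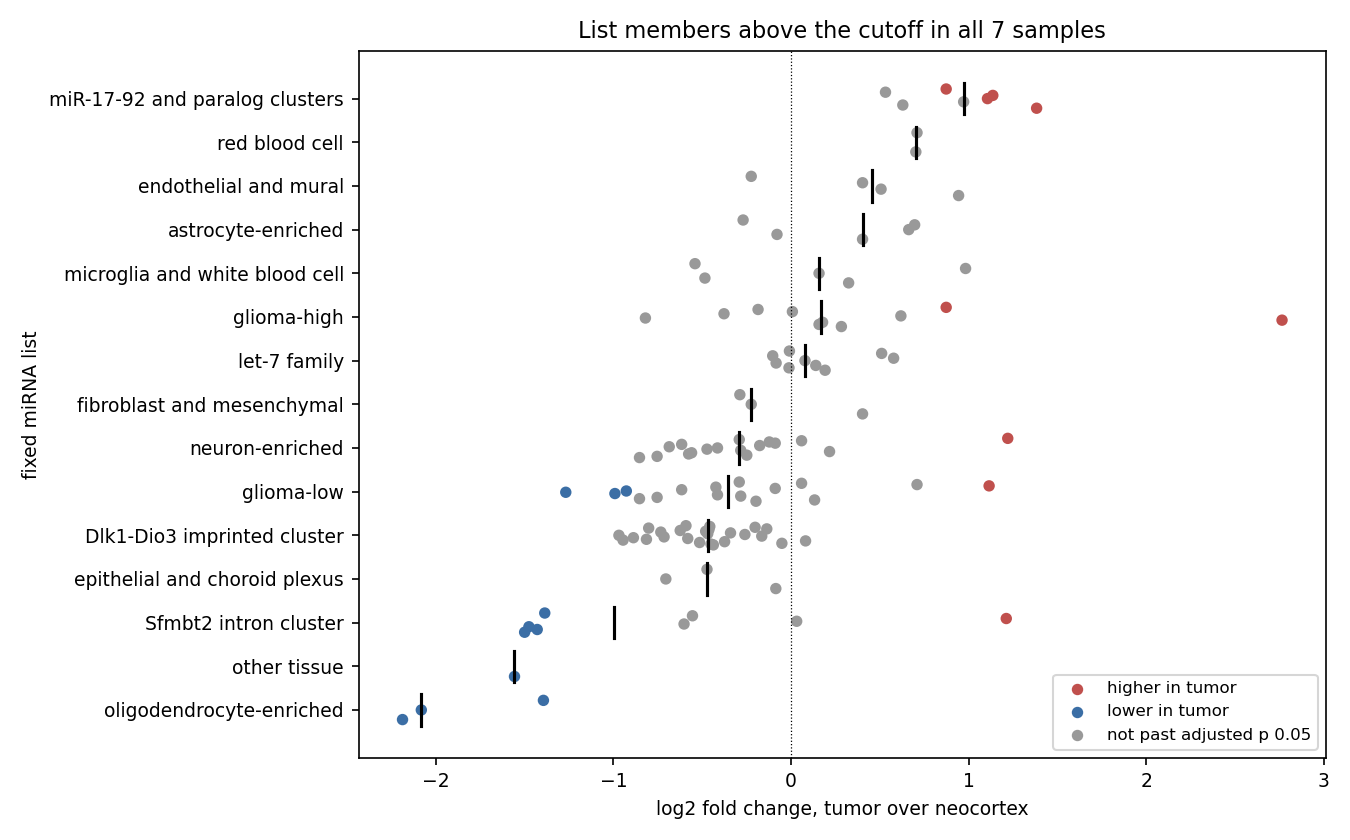
Log2 fold change of tumor over neocortex for the members of 15 miRNA lists that were above the cutoff in all 7 samples; each point is 1 miRNA, red or blue where it was higher or lower at a limma Benjamini-Hochberg adjusted p under 0.05, gray otherwise, and the black line is the median of the plotted members. The oligodendrocyte-enriched median is -2.08 and that of miR-17-92 and its paralogs 0.97. On the positive-control or housekeeping probes the median of all tested miRNAs moves from 0.03 to 1.74 or -0.93, so points nearer to 0 than that shift change side, miR-297c and miR-466g with the first and miR-7a with the second.

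Imprinted and repeat-derived miRNA clusters and the let-7 family complete the lists. In the Sfmbt2 intron cluster, a large rodent array of closely related miRNAs, 4 of 14 tested members were lower and 1 higher (the same counts adjusted over the list alone), with a median of 0.43, or -0.62 over the 6 tested with the shared cutoff, a mean of 0.50, a camera direction of down and an adjusted p of 0.74 (Benjamini-Hochberg). miR-297c fell by 1.43 on the log2 scale (SE 0.26, adjusted p = 0.015 in limma, Benjamini-Hochberg; 0.054 without tumor 2), and miR-669f rose by 1.21 (SE 0.17, adjusted p = 0.0079 in limma, Benjamini-Hochberg). Members of this cluster are near-identical in sequence, so the value of each probe is uncertain, and 3 of the 4 lower ones had a mean under 50 counts in neocortex. The Dlk1-Dio3 imprinted cluster, expressed in neurons, had 25 of 35 tested members below 0 and 0 called in limma (0 adjusted over the list alone; 4 lower at an unadjusted p under 0.05), with a median of -0.41, a mean of 0.07, a camera direction of down and an adjusted p of 0.24 (Benjamini-Hochberg). With the shared cutoff 3 of 26 tested members of the cluster were lower and 0 higher in limma, and camera gave an adjusted p of 0.078 (Benjamini-Hochberg). As listed, miR-136 and miR-127 differed by -0.45 and -0.44. Without neocortex 1 the cluster's camera adjusted p was 0.0063 (Benjamini-Hochberg), and miR-127 lay at -0.83 (adjusted p = 0.015 in limma, Benjamini-Hochberg). The 9 let-7 miRNAs had a median of 0.08 with 0 calls in limma (0 adjusted over the list alone; 1 higher at an unadjusted p under 0.05) and a camera adjusted p of 0.59 (Benjamini-Hochberg); let-7c and let-7g differed by 0.14 and -0.10.

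The other large falls were mostly in miRNAs counted at low numbers. miR-670 changed by -1.58, miR-1839-3p by -1.53, the probe of miR-297a, miR-466f and miR-669b by -1.50, miR-345-3p by -1.49 and miR-466g by -1.48, with limma Benjamini-Hochberg adjusted p between 0.0085 and 0.028. With NEG_D subtracted and the shared cutoff applied, miR-670 and miR-345-3p were still lower, by 1.25 and 1.46, miR-466g differed by -0.29 (SE 0.17, adjusted p = 0.27 in limma, Benjamini-Hochberg), and the other 2 were too low to test. Scaled on the positive-control probes, all 5 of these and miR-297c and miR-291b-3p lay above 0. miR-375, an islet and neuroendocrine miRNA, was at 4.88 to 6.12 in neocortex, at 0 in tumor 1 and 3, and at 3.24 and 3.26 in tumor 2 and 4; its adjusted p of 0.048 in limma (Benjamini-Hochberg) rose above 0.05 without any single sample but tumor 4, up to 0.13, and was 0.064 with median scaling, 0.056 in the trend and robust fit and 0.076 with a pseudocount of 0.5. Of the 27 lower miRNAs, 16 had a mean under 50 counts in neocortex and 11 had more. The probe of miR-297a, miR-466f and miR-669b had an adjusted p of 0.082 with the shared cutoff (limma, Benjamini-Hochberg) and of up to 0.074 without tumor 2, 3 or 4, and miR-670 of 0.054 without tumor 2 and 0.052 with median scaling. For miR-345-3p it was 0.059, 0.070, 0.071 or 0.055 without neocortex 2, neocortex 3, tumor 2 or tumor 3 (limma, Benjamini-Hochberg).

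Among the 23 higher miRNAs, 8 were at 0 in all 3 neocortex samples and above the cutoff in all 4 tumors, so their folds are lower bounds. Taking the tumor mean as it stands against the mean neocortex cutoff, miR-2133 was at least 1.88-fold higher in tumor, miR-709 at least 1.80-fold, miR-146a at least 1.75-fold, miR-804 at least 1.32-fold, miR-2137 at least 1.19-fold, miR-762 at least 1.10-fold and miR-2132 at least 1.09-fold. These bounds leave out the spread between tumors. The lower 95% limit of the tumor mean lay above the mean cutoff for miR-146a alone, at 5.23. For the others it ran from 1.21 for miR-2133 to 4.52 for miR-709. The tumor means of miR-2137, miR-762 and miR-2132 also lay under the cutoff of neocortex 3, 5.21. For the probes of miR-2133 and miR-2132 the GRCm38.p6 table held no miRNA gene of that name. The bounds of miR-2133, miR-2137, miR-762 and miR-2132 rest on tumor 1: without it their tumor means were 4.397, 4.627, 4.640 and 4.880, under the mean cutoff of 4.91. Without tumor 2 the bound of miR-2133 was 3.07. That of miR-2132 rests on neocortex 1 as well, since the mean cutoff without it, 5.045, lay above the tumor mean, 5.035. The adjusted p of the 8 ran from 2.2e-05 for miR-146a to 0.046 for miR-2133 (limma, Benjamini-Hochberg). These p-values set the tumor level against a listed 0 that has no spread among the neocortex samples. They therefore do not measure a difference from the neocortex level, which is unknown under the cutoff. miR-196a had a tumor mean of 4.90, under the mean cutoff, and has no fold; leaving out neocortex 3, tumor 3 or tumor 4 would give it a bound of 1.10, 1.03 or 1.09. With the shared cutoff miR-709, miR-146a and miR-804 did not pass the test, with adjusted p of 0.26, 0.086 and 0.21 (limma, Benjamini-Hochberg), and the other 5 were too low to test. In simulated data with no change, the fit to values as listed made a mean of 10.8 higher calls per run, and 0.05 with the shared cutoff. The miR-2133 mean rests on tumor 1, at 10.12 against 3.71 to 4.87 in the other tumors, and its adjusted p was up to 0.10 when any sample but tumor 1 was left out, and 0.11 with quantile scaling, just above 0.05 with the negative-control mean subtracted, and 0.15 or 0.23 with a pseudocount of 10 or 30 (limma, Benjamini-Hochberg).

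The top 3 miRNAs were partly the same in both tissues. miR-720 and miR-125b-5p were among the top 3 in each, with miR-124 as the third in neocortex and miR-9 in tumor. miR-720 had log2 means of 13.33 ± 0.18 in neocortex (SD, n = 3) and 13.11 ± 0.24 in tumor (SD, n = 4), and miR-125b-5p 12.98 ± 0.11 and 13.24 ± 0.16; neither passed the test.

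The 4 tumors differ in age, with 1 tumor per age, and a trend with age was not tested. At postnatal days 65, 104, 125 and 134, miR-21 was at 12.20, 11.40, 12.19 and 12.16, miR-9 at 13.02, 13.56, 13.11 and 13.19, miR-219 at 9.10, 8.47, 9.60 and 9.68, and miR-338-3p at 9.54, 9.28, 10.07 and 10.53. The lowest miR-219, miR-338-3p and miR-21 values and the highest miR-9 value were in the female tumor of day 104, with 1 female sample per group. All tumors were older than the neocortex samples, and genotype, tissue, age and total miRNA counts differ together between the groups. The 4 tumors differ in age and so came from different animals, and neocortex 2, a female, came from another animal than the male neocortex 1 and 3. The labels do not state that neocortex 1 and 3 came from separate animals, so the spread between those samples may be technical. The p-values measure the spread between the samples measured here.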

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

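The tests on miRNAs at 0 in neocortex were chosen only after the result was seen. In 35 splits of the 7 samples into 3 and 4, only the real split, 1 of 35, gave as many calls, 50 with the values as listed and 56 with the shared cutoff. The highest other split gave 0 in both cases, but every other split mixes the groups. As 1 of 35 is the smallest share this design can give, the splits argue against chance assignment only to that extent. Factors that go with the groups, such as total miRNA counts, cannot be excluded by them.

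Among 54 sets of 4 tumor values, 7 had a tumor far from the other 3, and chance marks about 1 in 20. Tumor 1, the youngest, stood above the others for miR-142-3p at 7.33, miR-762 at 6.30, miR-126-3p at 11.11, miR-128 at 10.57 and miR-155 at 8.16, and below them for miR-146a at 5.26. Tumor 2 was low for miR-21 at 11.40. For miR-34c the female tumor lay 2.45 above the female neocortex sample, 7.71 against 5.26, while the male tumors at 6.87, 7.59 and 7.95 lay below both male neocortex samples at 9.68 and 9.07; this difference was not tested.

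Of the panel's mRNA probes, those used here for scaling had tumor means of 9.66 for Actb, 7.71 for Gapdh and 7.87 for Rpl19, above the neocortex means of 8.60, 6.98 and 6.78. B2m, a subunit of MHC class I, was not used for scaling. It was at 4.84, 4.88 and 0 in the neocortex samples, where 0 stands for any level under the cutoff. In the tumors it was at 7.15 to 7.92, with a mean of 7.57. Of 33 probes for viral miRNAs, a mean of 15.25 lay above the cutoff in tumor and 1.33 in neocortex, and the highest tumor mean of such a probe was 4.14, under every neocortex cutoff.

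Outside the tested set, 42 untested miRNAs were at 0 in all neocortex samples and above the cutoff in all tumors. With the 8 called ones this makes 50 of the 566, and none showed the opposite. Of the 33 viral probes, 5 had the same pattern, all 5 with a tumor mean under the mean neocortex cutoff. The pattern by itself is therefore no sign of a higher level in tumor. The higher neocortex cutoff could account for most of the 50 miRNAs: 43 of them had a tumor mean under the mean neocortex cutoff. It argues less well for miR-146a, the only 1 whose lower 95% limit of the tumor mean, 5.23, lay above the highest neocortex cutoff, 5.21. At the tumor mean miR-146a would have given 29.4, 17.9 and 11.3 counts in the neocortex samples, where the cutoffs were 14, 10 and 8. A higher miR-146a in tumor stays a hypothesis, since it was picked from 50 miRNAs by a margin of this size and did not pass the test with the shared cutoff.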

How the results depend on the processing

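The settings with the shared cutoff, with miRNAs above the cutoff in all 7 samples and with the negative-control probe NEG_D subtracted before the shared cutoff were chosen after the data were seen. Scaling on the median, on the 100 brightest miRNAs or by quantiles, subtraction of the negative-control mean, pseudocounts of 0.5, 10 or 30 and the trend and robust fit kept both counts of calls within 1.5 times 23 higher and 27 lower. Up to 2 of the 24 called miRNAs named by the rule lost their call under each. Over all calls the losses were larger: median scaling kept 20 of the 23 higher and 20 of the 27 lower, and quantile scaling 20 and 19. The trend and robust fit kept 23 and 21. A sign change between fits in which neither value was called was not counted as a reversal. The cause was not tested for the changes below except where the setting itself alters the miRNAs or samples. No count model was run, as the values are on a log scale.

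Positive-control scaling gave 228 higher and 0 lower calls (231 and 0 at an unadjusted p under 0.05 in limma). It turned the sign of let-7g to 1.61, miR-124 to 0.86, miR-127 to 1.28, miR-128 to 0.96, miR-136 to 1.26, miR-137 to 1.43, miR-145 to 1.49, miR-150 to 1.23, miR-342-3p to 1.17, miR-720 to 1.48, miR-1839-3p to 0.18, miR-291b-3p to 0.15, miR-297c to 0.28, miR-345-3p to 0.22, miR-466g to 0.24, miR-670 to 0.14 and the miR-297a, miR-466f and miR-669b probe to 0.21. List medians became 1.93 for epithelial and choroid plexus, where camera's direction turned, 1.94 for raised in gliomas and 2.07 for other tissue, all past the threshold. Housekeeping scaling gave 10 higher and 135 lower calls, turned miR-7a to -0.90, and took camera's call from miR-17-92 and paralogs, at a median of 0.012, and from oligodendrocyte-enriched, at -3.04.

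With no filter 61 miRNAs were higher (459 tested) and the lowered-in-gliomas list passed at a median of -0.29. The planned stricter filter required a higher value in 3 samples only, tested 316 miRNAs and called 50 higher. Sex as a covariate gave 15 higher calls. Male samples only gave 6 lower calls and ended the oligodendrocyte-enriched call at a median of -1.98. With the shared cutoff, a log2 change of at least 1 left 9 higher and 14 lower calls, and leaving out neocortex 3 left 15 higher. Leaving out tumor 1 there moved Dlk1-Dio3, at -0.57, past the threshold. Keeping miRNAs above the cutoff in all 7 samples gave 41 lower calls, and subtracting NEG_D and then applying the shared cutoff 38 higher and 13 lower of 164, against 23 and 33 of 204 with the shared cutoff alone. The estimated correlation ended camera's calls of oligodendrocyte-enriched (-2.08) and miR-17-92 and paralogs (0.97). In fry, which does not compare a list with other miRNAs, the lists of microglia and white blood cells (0.32), raised in gliomas (0.23) and lowered in gliomas (-0.35) passed as well.

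Leaving out each sample in turn gave 13 to 32 higher and 10 to 41 lower calls. Neocortex 1 (41 lower without it), neocortex 3 (14 lower), tumor 2 (13 higher, 10 lower), tumor 3 (13 higher, 16 lower) and tumor 4 (15 higher) moved a count by over 1.5 times. List medians ranged from -2.31 to -1.89 for oligodendrocyte-enriched, which lost the call without neocortex 1, neocortex 2 or tumor 1, from 0.86 to 1.11 for miR-17-92 and paralogs, which lost it without neocortex 2, and from -0.69 to -0.21 for Dlk1-Dio3, which passed without neocortex 1. The fits without tumor 1 and without tumor 4 left out the youngest and the oldest tumor. They do not adjust for age, since every tumor was older than the neocortex samples.

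The replicate block left 5 higher and 0 lower calls (28 and 31 at an unadjusted p under 0.05 in limma). Tumor 4 has no neocortex sample of its number, so it did not contribute to the differences in that fit. Same-numbered samples had deviations correlated at -0.04, -0.03 and 0.06, and the others at -0.11 to 0.19. These values gave no sign that the numbers pair the samples. They cannot exclude it, since the deviations are taken from means of so few samples. The number of counts limits low probes in neocortex, where 1 count was worth up to 4.64 linear units.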

Other observations

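The tests of the oligodendrocyte-enriched list and the interval required of the background slope were chosen only after the result was seen, the other tests of background counts before their own results. Some choroid plexus and ciliated-cell miRNAs differed widely among the neocortex samples. miR-204, abundant in choroid plexus, was at 12.65, 9.10 and 9.64 in neocortex 1, 2 and 3 and at 9.72 to 10.84 in the tumors. miR-34c, of the miR-34b and miR-34c cluster active in ciliated cells, was at 9.68, 5.26 and 9.07 in neocortex and at 6.87 to 7.95 in the tumors. miR-34b-5p and miR-34b-3p, chosen after their values were seen, were at 6.99, 0 and 6.67 and at 7.32, 5.02 and 6.53 in neocortex. Of the 566 probes, 34 had no miRNA gene of that name in the GRCm38.p6 table, and 14 of these were tested. Of the 14, miR-2133, miR-2132 and miR-1944 were called higher and miR-2183 lower, the last 2 chosen after their values were seen, and miR-720, the most abundant probe in neocortex, was among them too.

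The fall of the oligodendrocyte-enriched miRNAs was set against dilution of all resident brain cells by the same share and against the scaling factor of each sample. If neuron-enriched miRNAs come from resident cells only, equal dilution predicts no larger fall than in them. The oligodendrocyte mean less the mean of 17 neuron-enriched miRNAs differed by -1.61 between tumor and neocortex (SE 0.36, 2-sided exact permutation p = 0.0286, the smallest possible). Without miR-338-5p, for which background and a real fall cannot be told apart, it was -1.86 (SE 0.49, exact permutation p = 0.0571), past its spread but not past 0.05. Relative to the median of all miRNAs above the cutoff in all 7 samples the list differed by -1.78, which no single factor per sample can alter, but on the positive-control probes its members lay at -0.48, -0.37 and 0.32 and none passed the test. Equal dilution is thus argued against only if tumor cells lack the neuron-enriched miRNAs, and less firmly without miR-338-5p. Whether they lack them was not tested, and miR-9, among the 17, was higher in tumor by 1.22. A fall in level and the authors' scaling cannot be told apart, since no value shows which scaling is right, and tissue, genotype and age stay open and untested.

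Low-count miRNAs that fell could reflect a constant number of background counts, which the larger factors of the neocortex samples would raise on the normalized scale. For the 11 lower miRNAs with 50 or more counts in neocortex this is argued against, since 10 of the 11 calls were left with the negative-control probe NEG_D subtracted and the shared cutoff applied. Of the 16 with fewer counts, 3 could be tested then: miR-291b-3p stayed called, at -0.63 (SE 0.19) against -1.56 (SE 0.21) before, while miR-466g and miR-532-3p, the latter chosen after its values were seen, went from -1.48 (SE 0.27) and -0.99 (SE 0.19) to -0.29 (SE 0.17) and -0.43 (SE 0.23) and lost their calls as the differences shrank. For the 15 of them above the cutoff in all samples the median slope within groups on the positive-control level was 0.521, past the 0.5 set in advance for background, but its 95% bootstrap interval ran from -0.0005 to 0.87 and 88 equally low miRNAs not called lower had a median of 0.52; the interval was made a requirement only after the value was seen. NEG_D was the only negative-control probe above the cutoff in neocortex, so subtracting it was the strongest such correction there. With the negative-control mean subtracted instead, where probes under the cutoff counted as 0, 26 of the 27 lower calls were left. For the 13 that could not be tested with NEG_D subtracted, background and a real fall cannot be told apart, because too few counts remain.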
